A study of Arabidopsis thaliana with 9 samples.

How the data were processed

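The series holds 9 RNA-seq libraries of whole Arabidopsis seedlings, 3 each of Col-0, ataf2-2 and ATAF2ox-3, grouped by the submitters' sample titles. Reads were aligned with HISAT2 2.1.0 to TAIR10 and handled with SAMtools 1.9, and transcripts were quantified with StringTie 2.1.4, per the submitters' processing notes. StringTie was run on a fixed set of Araport11 gene models with a setting for stranded libraries, per the file headers. Trimming, read length and read number are not given in the sources used here.

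Each deposited file lists, per transcript, coverage, FPKM and TPM as the authors' StringTie run wrote them, and coverage per exon. TPM in the deposited files sums to 1e+06 in each library, and FPKM is scaled to the bases aligned. The values are not counts of reads, so no count model was used. The deposited coverage and FPKM stand in a constant ratio within each library, and that ratio gave the bases aligned, between 4.23 and 5.80 gigabases, of which 89.8% to 91.4% fell in gene models. At this depth between 18680 and 19242 genes reached 1 TPM per library. Gene values are the sums over the transcripts of a gene; the files held 27654 genes and 48455 transcripts. All 27444 nuclear genes were found in the TAIR10.1 annotation, which gave gene products, and 27437 of them stood at identical positions there.

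Genes with a mean of at least 1 TPM over the 9 libraries were tested, 19045 in all. Log2(TPM + 0.5) was fitted with limma 3.58.1 in R 4.3.3, with all 9 libraries in 1 model that shares an estimate of the spread, moderated robustly with an intensity trend. The 3 contrasts between genotypes were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Fold changes are on the log2(TPM + 0.5) scale, which understates the change of low genes. The gene lists, 24 in number with 289 loci of which 258 were tested, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of each contrast. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

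The design, the gene lists, the rule for naming genes and all alternatives but 1 were set before the data were examined. The rule named ATAF2; among called genes whose groups do not overlap, the 8 largest rises and 8 largest falls of each contrast; and of each list, up to 4 called members with the smallest adjusted p. Of brassinosteroid inactivation, ethylene biosynthesis, nitrilases and the salicylic acid list it named up to 3 tested members with the smallest adjusted p whether called or not, and of genes changed in both lines up to 5 per direction. A gene named by the rule could be left out for space. Other list members named in the text (COBL9, RHD6, PRP3, EXPA18, WRKY40, ZAT10, BHLH38 and IRT1, and LTI30, NAC6 and NIT3 in the comparison of ATAF2ox-3 with Col-0), and EXT3 and AT1G19900 in that of ataf2-2 with Col-0, were chosen after their values were seen. Groups of 3 against 3 do not overlap for 10% of genes by chance; they did not overlap for 12.4%, 11.8% and 18.0% of genes in the contrasts of ataf2-2 with Col-0, ATAF2ox-3 with Col-0 and ATAF2ox-3 with ataf2-2.

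The fit was tested on simulated data, in which residuals of the real libraries were mixed at random so that genes kept their correlation, with 200 of 19045 genes changed in each of 10 runs. For ataf2-2 against Col-0 it found 55.2% of genes changed by 1 on the log2 scale and 91.5% of those changed 4-fold. For ATAF2ox-3 against Col-0 these were 52.9% and 89.3%, and for ATAF2ox-3 against ataf2-2 49.6% and 86.3%. The real contrasts called 16, 29 and 135 genes. Where fewer genes change than were planted, the adjusted threshold is stricter, so these shares may overstate what the real fit finds. False calls made up 1.41%, 0% and 0.902% of calls in the 3 contrasts. In 100 simulations with no gene changed, calls were made in 4 for ataf2-2 against Col-0 and in 4 for ATAF2ox-3 against Col-0. The median was 0 calls, but the highest counts were 5088 and 8421 genes, so false calls were rare but could be many at once. With no list changed, camera at the preset correlation called a median of 6, 7 and 6.5 of 24 lists in the 3 contrasts over 50 runs, while with an estimated correlation at least 1 list was called in 2%, 0% and 2% of runs. A shifted list in the contrast of ataf2-2 with Col-0 was found in 98% of runs with the preset and in 60% with the estimated correlation.

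Although the header names a stranded setting, genes lying inside an unspliced gene on the other strand had a median of 0.548 to 0.626 of its coverage across libraries, against 0.0247 to 0.0394 inside spliced genes. Reads of overlapping genes on opposite strands were therefore not fully separated, and 1469 genes share at least 20% of their exonic bases with such a partner. Alternatives changed the pseudocount, the filter, the scaling, the unit, the moderation, the libraries in the fit, a replicate block, library weights and the threshold, and left out each library in turn; the one without overlapping genes was chosen after seeing the data. No pair of libraries held the same values.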

Results

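RNA was sequenced from whole Arabidopsis thaliana seedlings of 3 genotypes, with 3 libraries each. Per the labels, all seedlings were 4 days old, had been stratified for 4 days and were kept in light of 10 uE. Col-0 is the wild-type accession. The line ataf2-2 is described as a loss-of-function mutant of ATAF2, a transcription factor of the NAC family, and ATAF2ox-3 as a gain-of-function line of the same gene. The depth, recovered from the deposited coverage and FPKM values, was 5.80, 4.97 and 4.96 gigabases aligned for Col-0 replicates 1 to 3. It was 5.17, 4.23 and 4.69 gigabases for the libraries labelled ataf2-2, and 4.79, 4.998 and 4.90 for ATAF2ox-3. The labels do not say whether replicates were grown separately, so the p-values measure only the spread between these libraries, which may be technical.

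The targeted gene was read first in every library. ATAF2 (AT5G08790, chromosome 5, 2858849 to 2860558, minus strand, TAIR10) measured 25.6, 23.9 and 19.2 TPM in Col-0. It measured 56.9, 60.7 and 58.8 TPM in the libraries labelled ataf2-2, and 279.1, 285.7 and 261.6 TPM in ATAF2ox-3. ATAF2 RNA was therefore higher, not lower, in the libraries labelled ataf2-2, by 1.35 on the log2 scale (SE 0.12, adjusted p = 0.00175, limma). In ATAF2ox-3 it rose by 3.57 over Col-0 (SE 0.12, adjusted p = 7.77e-07, limma) and by 2.22 over the libraries labelled ataf2-2 (SE 0.12, adjusted p = 3.65e-05). The level in the libraries labelled ataf2-2 therefore does not bear out their loss-of-function label. RNA level alone cannot show whether the protein works, so it does not contradict the label either, and each direction given for these libraries stands under that limit.

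The 3 exons of ATAF2 did not rise evenly. Exon 1 (2859985 to 2860558), with the 5' untranslated region and the first coding bases, had a mean coverage per gigabase aligned of 7.24 ± 1.29 (SD, n = 3) in Col-0 and 26.7 ± 2.96 in libraries labelled ataf2-2. Exon 2 (2859615 to 2859895), which is coding throughout, had 23.9 ± 2.80 and 50.8 ± 6.94. Exon 3 (2858849 to 2859523), with the last coding bases and the 3' untranslated region, had 14.9 ± 2.91 and 35.6 ± 7.34. The ratio of exon 1 to exon 2 was 0.301 ± 0.0224 in Col-0, 0.527 ± 0.0233 in libraries labelled ataf2-2 and 0.237 ± 0.0120 in ATAF2ox-3. The ratio of exon 3 to exon 2 ranged from 0.563 to 0.668 in Col-0 and from 0.485 to 0.953 in libraries labelled ataf2-2. In ATAF2ox-3 it ranged from 0.396 to 0.429, so the exon profile of that line differed from Col-0 too.

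**Figure D1:**
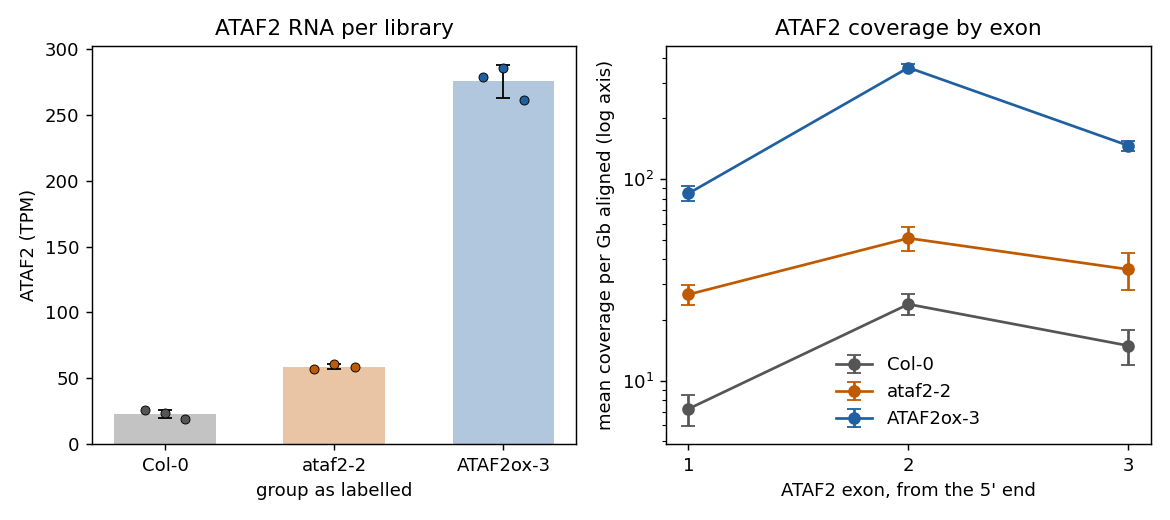
Left, ATAF2 RNA in TPM per library (points), with the mean (bar) and SD (whisker) of 3 libraries per group. Right, mean coverage of each ATAF2 exon per gigabase aligned on a log axis, with the SD; exon 1 was 3.69 times and exon 2 2.12 times higher in libraries labelled ataf2-2 than in Col-0.

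The comparison of ataf2-2 with Col-0 asks which genes differ in the line described as a loss-of-function mutant of ATAF2. CYP72C1 (AT1G17060), a cytochrome P450 that inactivates brassinosteroids, rose from 1.14 ± 0.174 TPM in Col-0 to 14.8 ± 3.02 in libraries labelled ataf2-2 (SD, n = 3). HEI10 (AT1G53490), a gene of meiotic crossing-over, rose from 1.91 ± 0.179 to 19.2 ± 1.66 TPM, and the overlapping MRD1 (AT1G53480) from 0.565 ± 0.556 to 33.5 ± 3.36. AT4G15160 (chromosome 4, 8646150 to 8647252), annotated as a lipid-transfer protein, rose from 8.61 ± 1.60 to 80.2 ± 32.4 TPM. The expansin gene EXPA8 (AT2G40610, chromosome 2, 16948791 to 16950705) fell from 309.6 ± 8.05 to 149.5 ± 14.0 TPM, and RGF9 (AT5G64770), which encodes a root meristem growth factor, from 233.7 ± 44.1 to 89.2 ± 11.6.

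In all, 16 of 19045 genes tested passed limma's threshold, 13 higher and 3 lower in libraries labelled ataf2-2, and in each of the 16 the libraries of one genotype all lay above those of the other. An unadjusted p under 0.05 was reached by 1399 genes, where chance gives 952. The log2 changes were 3.21 for CYP72C1 (SE 0.23, adjusted p = 0.000556, limma), 3.04 for HEI10 (SE 0.16, adjusted p = 7.45e-05) and 5.14 for MRD1 (SE 0.41, adjusted p = 0.000870). AT1G17065 (3.17), AT4G15160 (3.09), AT3G59710 (1.95), AT5G08760 (1.66) and the beta-glucosidase gene BGLU21 (1.39) were the other named rises. Of these, AT5G08760 (chromosome 5, 2854857 to 2855617) lies near ATAF2 (2858849 to 2860558). It measured 4.92 to 7.04 TPM in ATAF2ox-3 and 4.33 to 6.48 in Col-0. Whether its rise in libraries labelled ataf2-2 is tied to that of ATAF2 was not tested. The falls measured -1.05 for EXPA8, -1.37 for RGF9 and -1.45 for the peroxidase gene AT2G41480. AT1G17065 shares 90.2% of its exonic bases with CYP72C1 on the opposite strand, and MRD1 73.8% with HEI10, so their reads could not be fully told apart and these rises are uncertain for each gene singly. With genes that share at least 20% of their exonic bases left out, an alternative chosen after seeing the data, 8 genes passed, 6 higher and 2 lower. Of the 16 calls, 5 were of genes then left out (CYP72C1, AT1G17065, HEI10, MRD1 and EXT3), and 3 did not pass (AT2G41480 and AT3G59710, both with an adjusted p of 0.0619 in limma, and AT1G19900 with 0.0640).

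CYP72C1 (chromosome 1, 5832094 to 5835488, minus strand) rose unevenly along its length. Its 3 exons at the 3' end went from 0.239 ± 0.103 to 11.2 ± 2.64 coverage per gigabase aligned in libraries labelled ataf2-2, and its 2 exons at the 5' end from 1.43 ± 0.156 to 4.89 ± 0.804 (SD, n = 3). HEI10 (chromosome 1, 19963267 to 19966952, plus strand) went from 0.620 ± 0.358 to 18.9 ± 1.68 inside the span of MRD1 (19963047 to 19964712), and from 1.18 ± 0.271 to 3.48 ± 0.163 outside it.

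**Figure D2:**
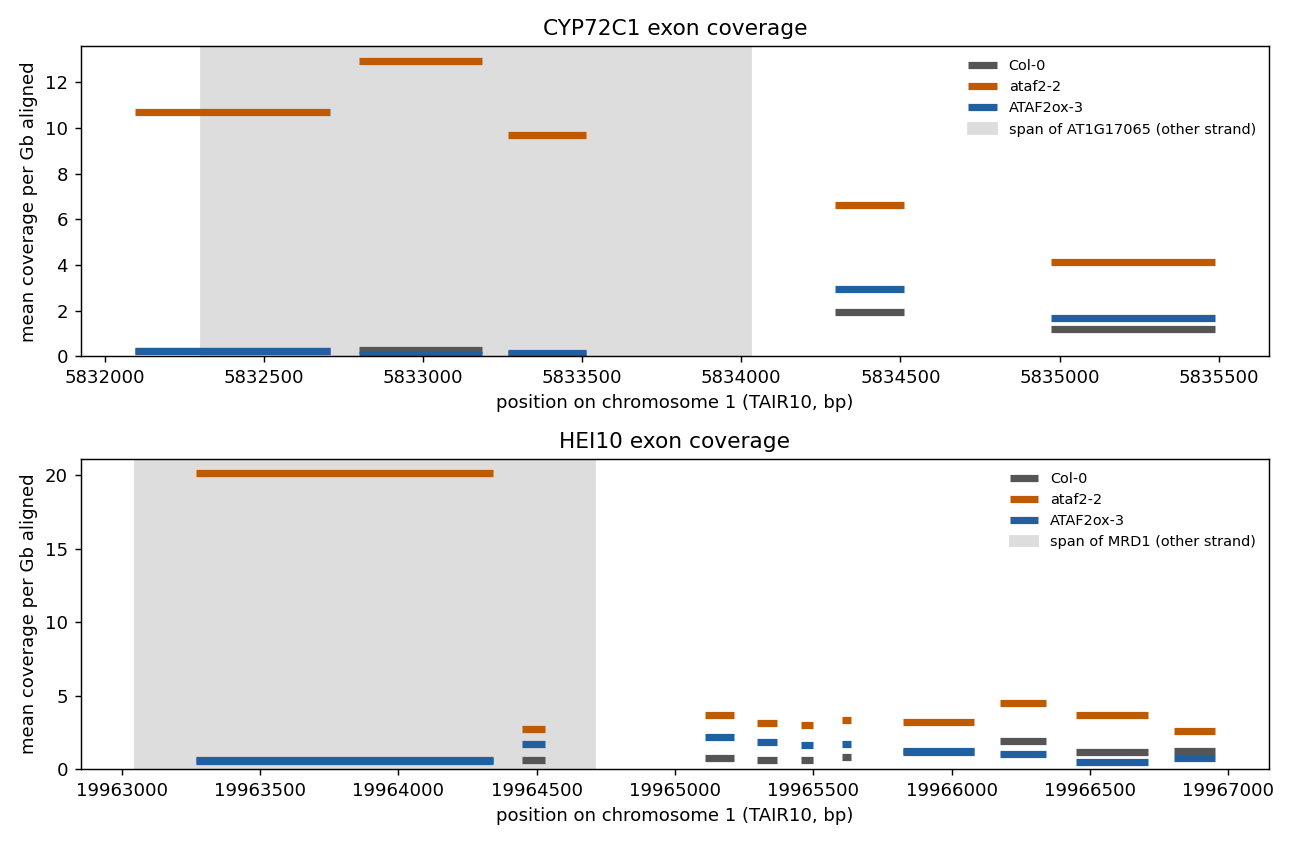
Mean coverage per gigabase aligned (n = 3 libraries per group) of each exon of CYP72C1 and HEI10 along chromosome 1 in TAIR10 coordinates, with the span of the gene on the other strand shaded. In libraries labelled ataf2-2 the 3' exons of CYP72C1 reached 11.2 and the HEI10 exons inside the MRD1 span 18.9.

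Part of these calls was lost on leaving out 1 library, with log2 changes between 0.900 and 1.06 times those from all 9 libraries and standard errors 1.13 times as large in the median. The count was 9 without Col-0 replicate 3, 10, 32 and 9 without the libraries labelled ataf2-2 replicate 1, 2 and 3, and 9 without ATAF2ox-3 replicate 1. CYP72C1, AT1G17065, AT4G15160, HEI10 and MRD1 passed whichever of the 9 libraries was left out, with adjusted p of 0.0430 or less in limma; MRD1 did not pass with a pseudocount of 0.1 (adjusted p = 0.0528) or with voom (0.0543). Of the 11 named calls other than ATAF2, 5, 3 and 5 were lost without Col-0 replicates 1, 2 and 3 (adjusted p up to 0.163, 0.115 and 0.156, limma). Without the libraries labelled ataf2-2 replicate 1, 2 and 3 it was 6, 3 and 6 (up to 0.195, 0.0646 and 0.189), and without ATAF2ox-3 replicate 1 it was 5 (up to 0.0721). EXPA8 did not pass without Col-0 replicate 1 (adjusted p = 0.0568, limma) or without the libraries labelled ataf2-2 replicate 1 (0.0546) or 3 (0.0638). Other settings also ended the calls of AT2G41480 (adjusted p up to 0.0864, limma), RGF9 (0.0746), AT5G08760 (0.0659), AT3G59710 (0.0625) and BGLU21 (0.0566). The log2 changes of calls ended by other settings were 0.986 to 1.32 times those given, with standard errors 1.09 times as large in the median. That of AT1G17065, which kept its call, was 5.21 with a pseudocount of 0.1 and 6.95 with voom.

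Among the gene lists, few members passed singly in libraries labelled ataf2-2. Of 7 tested genes of brassinosteroid inactivation, CYP72C1 rose, over all genes and adjusted over the list alone, and 6 did not pass; BIA1 measured 2.97 ± 1.29 TPM in Col-0 and 5.12 ± 0.368 (adjusted p = 0.509, limma), and BAS1 9.28 ± 1.91 and 10.9 ± 2.74 (adjusted p = 0.958). Of 12 genes of ethylene biosynthesis 0 passed over all genes in limma, 5 had an unadjusted p under 0.05, and 2 higher and 3 lower passed when adjusted over the list alone. Of these, the ACC synthase genes ACS5 (11.7 ± 6.38 TPM in Col-0 against 1.86 ± 0.587; adjusted p over all genes 0.0831, limma) and ACS4 (8.59 ± 4.34 against 0.849 ± 0.889; 0.125) were on the lower side. The ACC oxidase gene ACO5 (AT1G77330; 43.0 ± 3.40 against 70.7 ± 12.2 TPM; 0.127) was on the higher side.

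Of the 4 nitrilases, enzymes of which some can form the auxin indole-3-acetic acid from its nitrile, 0 passed over all genes in limma, 2 had an unadjusted p under 0.05, and 1 higher and 1 lower passed when adjusted over the list alone. NIT2 measured 17.9 ± 3.10 TPM in Col-0 and 9.52 ± 3.44 in libraries labelled ataf2-2 (adjusted p = 0.248, limma), and NIT3 27.0 ± 4.59 and 46.0 ± 10.4 (adjusted p = 0.304). Of 9 salicylic acid and pathogenesis-related genes 0 passed over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. EDS5 measured 5.10 ± 0.811 TPM in Col-0 and 8.51 ± 1.14 (adjusted p = 0.605, limma), and ALD1 2.56 ± 0.762 and 4.42 ± 0.685 (adjusted p = 0.845). Tested as groups with camera, the lists of brassinosteroid inactivation (mean log2 change 0.55, median -0.05; adjusted p = 0.0627), ethylene biosynthesis (0.261), nitrilases (0.172) and salicylic acid (mean 0.06, median -0.12; 0.993) did not pass.

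As groups, 6 of 24 lists passed camera at a preset correlation of 0.01 between genes, and 0 with an estimated one. Simulated libraries with no list changed gave a median of 6, so the count is no larger than in unchanged data. Auxin response genes were lower in libraries labelled ataf2-2 (15 of 16 negative, mean log2 change -0.72, adjusted p = 8.48e-08; 1 lower adjusted over the list alone; adjusted p = 0.456 with an estimated correlation). Root tissue markers were higher (8 of 8 positive, mean 0.70, adjusted p = 1.28e-06; adjusted p = 0.284 with an estimated correlation), and 4 of them, COBL9, RHD6, PRP3 and EXPA18, passed when adjusted over the list alone. Iron deficiency genes were lower (8 of 9 negative, mean -0.98, adjusted p = 0.00111; 2 lower adjusted over the list alone), as were cell wall loosening genes (5 of 7 negative, mean -0.37, adjusted p = 0.00961; 1 lower over all genes and adjusted over the list alone). Both had an adjusted p = 0.284 with an estimated correlation. Abscisic acid and dehydration genes were lower (13 of 14 negative, mean -0.64, adjusted p = 0.000789) and brassinosteroid biosynthesis genes higher (9 of 10 positive, mean 0.21, adjusted p = 0.0365); both had an adjusted p = 0.456 with an estimated correlation, and 0 members of either passed when adjusted over the list alone. The 18 other lists had adjusted p between 0.0627 and 0.993.

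Root tissue markers were the 1 called list of these 6 whose means did not overlap between the libraries of both genotypes. Relative to the mean of all 9 libraries, auxin response genes stood at -0.68, 0.33 and -1.07 in the libraries labelled ataf2-2 replicate 1, 2 and 3 and at 0.27, 0.06 and 0.40 in Col-0, so that replicate 2 was not lower. Their mean log2 change was -1.12 without the library labelled ataf2-2 replicate 2 (adjusted p = 4.34e-18, camera) and -0.42 without replicate 3 (0.00181). Without Col-0 replicate 1 the mean of iron deficiency genes was -0.44 (adjusted p = 0.118, camera), and dehydration and brassinosteroid biosynthesis did not pass either (both 0.0711). The mean of dehydration genes was -0.99 without Col-0 replicate 2 (adjusted p = 1.33e-05) and -0.27 without the library labelled ataf2-2 replicate 1 (0.0663), and that of cell wall loosening -0.19 without Col-0 replicate 3 (0.0532). Brassinosteroid biosynthesis did not pass without Col-0 replicate 2 (0.161), without the library labelled ataf2-2 replicate 2 (mean 0.12, adjusted p = 0.288) or with a mean of at least 5 TPM (mean log2 change 0.18).

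The comparison of ATAF2ox-3 with Col-0 asks which genes differ when ATAF2 RNA is raised. NIT2 (AT3G44300, chromosome 3, 15983199 to 15985535) rose from 17.9 ± 3.10 TPM in Col-0 to 188.0 ± 21.3 in ATAF2ox-3 (SD, n = 3). The subtilase gene AT5G58840 (chromosome 5, 23759003 to 23762438) rose from 0.238 ± 0.116 to 15.4 ± 7.59 TPM, the peroxidase gene AT5G64120 from 40.0 ± 20.1 to 263.8 ± 59.4, and DTX1 (AT2G04040), which encodes an efflux transporter, from 1.13 ± 0.425 to 9.39 ± 1.70. The oxidoreductase genes ChlAKR (AT2G37770) and AT1G60750 rose from 0.886 ± 0.325 and 2.54 ± 1.35 TPM to 14.0 ± 8.66 and 15.4 ± 3.79. CYP81D11 (AT3G28740), a cytochrome P450 gene, fell from 28.8 ± 5.98 to 9.51 ± 2.15 TPM, and the glutathione transferase gene GSTU22 (AT1G78340) from 19.9 ± 2.73 to 8.65 ± 1.61.

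In limma 29 of 19045 genes passed, 27 higher and 2 lower in ATAF2ox-3, and in each of the 29 the libraries of one genotype all lay above those of the other; 1508 had an unadjusted p under 0.05. The split was 26 higher and 6 lower with median ratio scaling, 30 and 9 with quantile normalization and 27 and 7 with voom. NIT2 changed by 3.37 on the log2 scale (SE 0.23, adjusted p = 0.000530, limma), AT5G58840 by 4.34 (SE 0.33, adjusted p = 0.000648), AT5G64120 by 2.79 (SE 0.31, adjusted p = 0.00870), DTX1 by 2.62, ChlAKR by 3.26 and AT1G60750 by 2.48. CYP81D11 changed by -1.55 (SE 0.19, adjusted p = 0.0115, limma) and GSTU22 by -1.16 (SE 0.15, adjusted p = 0.0194). AT4G12490, annotated as a lipid-transfer protein, measured 85.4, 92.2 and 9.61 TPM in ATAF2ox-3 and 0.293, 0 and 0 in Col-0 (adjusted p = 0.0174, limma); it shares 35.9% of its exonic bases with a gene on the other strand. NIT2 stands in a cluster with NIT1 and NIT3, and AT1G60750 beside related genes; whether reads were shared between such copies was not tested, and their values are uncertain to that extent.

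**Figure D3:**
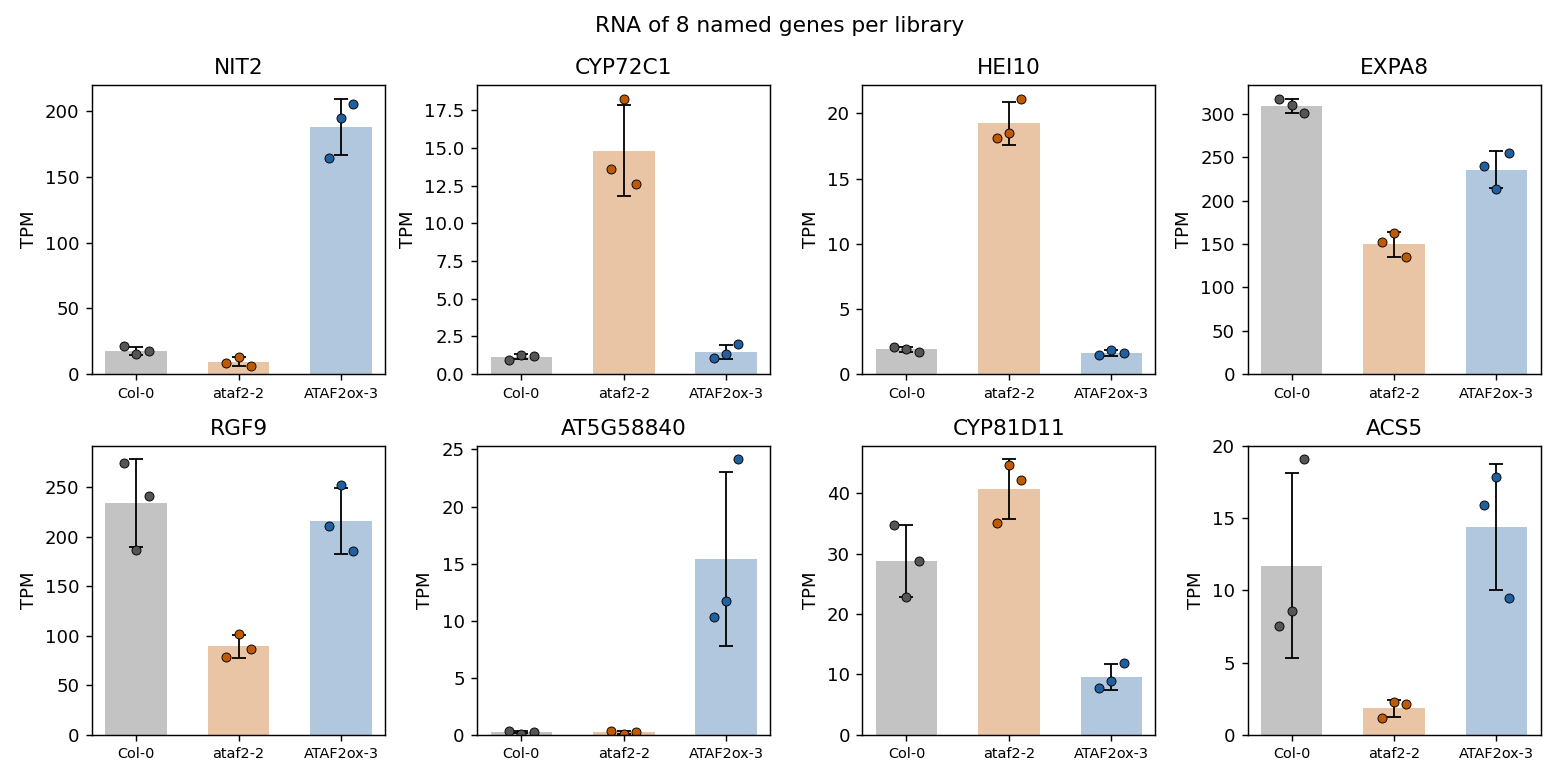
RNA in TPM of 8 named genes per library (points), with the mean (bar) and SD (whisker) of 3 libraries per group. NIT2 averaged 188.0 TPM in ATAF2ox-3 against 17.9 in Col-0 and 9.52 in libraries labelled ataf2-2, and CYP72C1 14.8 TPM in the last of these against 1.14 in Col-0.

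On leaving out 1 library, calls were again lost with log2 changes between 0.907 and 1.08 times those from all 9 libraries and standard errors 1.16 times as large in the median. The count was 16 without Col-0 replicate 2, 13 without Col-0 replicate 3, 8 without ATAF2ox-3 replicate 1, 62 without ATAF2ox-3 replicate 2 and 122 (56 higher, 66 lower) without ATAF2ox-3 replicate 3. NIT2 and AT5G58840 passed whichever of the 9 libraries was left out, with adjusted p of 0.00717 or less in limma. Of the 10 named calls other than ATAF2, 4, 4 and 8 were lost without Col-0 replicates 1, 2 and 3 (adjusted p up to 0.0757, 0.190 and 0.123, limma). Without ATAF2ox-3 replicates 1 and 2 it was 8 and 1 (up to 0.119 and 0.0690), and without the libraries labelled ataf2-2 replicate 1 and 3 it was 3 and 1 (up to 0.0897 and 0.0689). Other settings also ended the calls of AT4G12490 (adjusted p up to 0.595, limma), ChlAKR (0.235), AT1G60750 (0.123), CYP81D8 (0.0884), GSTU22 (0.0881) and AT5G64120 (0.0682). Their log2 changes were then no smaller, at 1 to 1.54 times those of the main settings, with standard errors 1.14 times as large in the median; AT4G12490 went from 6.21 to 9.58 (SE 3.92) with voom.

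Of 10 tested stress NAC genes, ATAF2 rose in ATAF2ox-3, and ATAF2 and NAC6 were higher when adjusted over the list alone. Of 4 nitrilases, NIT2 rose over all genes, and 2 were higher when adjusted over the list alone; NIT4 measured 2.59 ± 0.841 TPM in Col-0 and 6.23 ± 2.25 in ATAF2ox-3 (adjusted p = 0.351, limma), and NIT1 425.3 ± 72.7 and 441.7 ± 68.9 (adjusted p = 0.980). Of 9 detoxification genes, CYP81D8 rose from 1.82 ± 0.321 to 10.2 ± 4.47 TPM (adjusted p = 0.0252, limma), and 2 higher and 1 lower passed when adjusted over the list alone.

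No gene of brassinosteroid inactivation (7 tested), ethylene biosynthesis (12) or the salicylic acid list (9) passed in ATAF2ox-3 over all genes in limma or adjusted over the list alone. An unadjusted p under 0.05 was reached by 0, 1 and 1 of them. CYP72C1 measured 1.48 ± 0.477 TPM against 1.14 ± 0.174 in Col-0 (adjusted p = 0.885, limma), and BEN1 32.4 ± 4.82 against 38.0 ± 3.68 (adjusted p = 0.726). DOGT1 measured 3.18 ± 2.30 against 3.74 ± 0.592 TPM (adjusted p = 0.922, limma), ACS6 20.9 ± 12.4 against 7.71 ± 4.35 (adjusted p = 0.591), and PAD4 6.35 ± 2.05 against 3.48 ± 0.0780 (adjusted p = 0.421). Their lists did not pass camera (adjusted p = 0.281 for brassinosteroid inactivation, 0.480 for ethylene biosynthesis and 0.360 for salicylic acid).

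In camera 6 of 24 lists passed at the preset correlation and 0 with an estimated one, where simulated libraries with no list changed gave a median of 7. Nitrilases were higher in ATAF2ox-3 (4 of 4 positive, mean log2 change 1.14, median 0.58, adjusted p = 0.00529; adjusted p = 0.567 with an estimated correlation). Without NIT2 the mean of the other 3 was 0.40. NIT3 measured 0.03 and NIT1 0.057, where the median of all genes tested was 0.050, so neither stood out from the typical gene. NIT1 was below 0 with median ratio scaling (-0.0023), with library weights (-0.10), without Col-0 replicate 2 (-0.023) and without ATAF2ox-3 replicate 3 (-0.067). Touch and early wounding genes were higher (5 of 6 positive, mean 1.40, adjusted p = 0.00529; 2 higher adjusted over the list alone; adjusted p = 0.568 with an estimated correlation), with WRKY40 at 2.93 and ZAT10 at 2.21, neither past the threshold over all genes. Relative to the mean of all 9 libraries they stood at 1.41, -0.21 and 1.29 in ATAF2ox-3 replicates 1 to 3 and at -0.26, -0.90 and -0.56 in Col-0, so that ATAF2ox-3 replicate 2 lay close to Col-0 replicate 1. Iron deficiency genes were higher (7 of 9 positive, mean 1.39, adjusted p = 0.00948), and photosynthesis genes (17 of 23 negative, mean -0.14, adjusted p = 0.00948) and heat shock genes (5 of 6 negative, mean -0.37, adjusted p = 0.0314) lower. All 3 had an adjusted p = 0.568 with an estimated correlation, and 0 of their members passed when adjusted over the list alone. Abscisic acid and dehydration genes were lower (9 of 14 negative, mean -0.50, adjusted p = 0.0314; adjusted p = 0.696 with an estimated correlation), though the dehydrin gene LTI30, the 1 member past the threshold adjusted over the list alone, was higher (1.75). Median ratio scaling lowered genes in ATAF2ox-3 against Col-0 by about 0.059 on the log2 scale. With it the calls of photosynthesis (mean -0.20), heat shock (-0.43) and dehydration (-0.56) ended though their means were no smaller in size. They ended too with quantile normalization (-0.076, -0.41 and -0.55), those of heat shock and dehydration also with voom (-0.49 and -0.59), and that of dehydration also with FPKM (-0.51) and without a filter (-0.50). Library weights ended those of nitrilases (mean 0.96) and iron deficiency (1.42), and gave means of -0.22 for photosynthesis and -0.62 for heat shock, which kept their calls. The 18 other lists had adjusted p between 0.0631 and 0.946.

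The library means of both genotypes overlapped for 4 of these 6 lists, all but nitrilases and touch and early wounding. The mean of photosynthesis genes was -0.085 without Col-0 replicate 1 (adjusted p = 0.195, camera), -0.072 without Col-0 replicate 2 (0.197), -0.27 without Col-0 replicate 3 (6.04e-07) and -0.077 without ATAF2ox-3 replicate 2 (0.0314). That of dehydration genes was -0.32 without Col-0 replicate 1 (adjusted p = 0.328), -0.85 without Col-0 replicate 2 (0.00302) and -0.28 without ATAF2ox-3 replicate 2 (0.467). Heat shock genes averaged -0.20 without ATAF2ox-3 replicate 1 (adjusted p = 0.124) and -0.56 without ATAF2ox-3 replicate 3 (0.0144), and did not pass without Col-0 replicate 2 (0.199) or ATAF2ox-3 replicate 2 (0.05005). Iron deficiency did not pass without Col-0 replicate 3 (0.178).

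The lines were also compared with each other, which tests the difference between their changes. NIT2 was higher in ATAF2ox-3 than in libraries labelled ataf2-2 by 4.28 on the log2 scale (SE 0.23, adjusted p = 3.65e-05, limma). The ACC synthase genes ACS5 (14.4 ± 4.37 against 1.86 ± 0.587 TPM; log2 change 2.64, adjusted p = 0.0133, limma) and ACS4 (10.6 ± 5.01 against 0.849 ± 0.889 TPM; 3.15, adjusted p = 0.0370) were higher. Of the 12 tested genes of ethylene biosynthesis these 2 passed over all genes and 10 did not, and 3 higher and 2 lower passed when adjusted over the list alone; ACO5, on the lower side, measured 45.1 ± 3.17 against 70.7 ± 12.2 TPM (-0.63, adjusted p = 0.0855, limma). Of the 9 tested genes of the salicylic acid list, which does not hold PR4, 0 passed over all genes in limma, 4 had an unadjusted p under 0.05, and 1, ALD1, was lower adjusted over the list alone (-1.59, adjusted p over all genes 0.150). Also higher was IAA5, an auxin-induced gene (13.5 ± 1.43 against 2.27 ± 1.63 TPM; 2.48, adjusted p = 0.00953). PR4, a pathogenesis-related gene of the jasmonate and defensins list, was lower in ATAF2ox-3 at 31.3 ± 3.44 against 61.9 ± 1.097 TPM (-0.98, adjusted p = 0.00662, limma). The other 11 of the 12 tested genes of that list did not pass, 7 of the 12 were positive, and the list did not pass camera (adjusted p = 0.975). The latex protein-like gene MLP329 was also lower, at 25.9 ± 6.22 against 131.4 ± 24.5 TPM (-2.33, adjusted p = 0.00113, limma).

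In this contrast 135 genes passed limma's threshold, 81 higher and 54 lower in ATAF2ox-3; with median ratio scaling the split was 84 and 90. Further genes higher in ATAF2ox-3 than in libraries labelled ataf2-2 were AT5G58840 (log2 change 4.35), ChlAKR (3.97), AT3G19615 (3.60), AT5G50335 (3.21), CYP81D8 (2.85), LTI30 (1.77), NIT4 (1.63), NAC6 (1.15) and EXPA8 (0.66). This contrast alone does not show which line departed from Col-0. AT5G58840, ChlAKR, AT3G19615 and CYP81D8 also passed as higher over Col-0. EXPA8, however, measured 236.0 TPM in ATAF2ox-3, below the 309.6 of Col-0. AT5G50335 measured 13.2 to 23.0 TPM in ATAF2ox-3 and 18.9 to 25.9 in Col-0. AT4G12490 and AT4G12495 were higher too, but AT4G12495 lies wholly within the exons of AT4G12490 on the other strand and both are uncertain. AT3G19615 is uncertain too, as it shares 26.9% of its exonic bases with AT3G19613 on the other strand. Further genes lower in ATAF2ox-3 were MRD1 (-5.29), AT3G16670 (-3.41), HEI10 (-3.20), AT1G17065 (-3.08), CYP72C1 (-2.96), AT1G50060 (-2.50), AT3G59710 (-2.23) and OPR1 (-1.26). MRD1 and HEI10, and AT1G17065 and CYP72C1, are the overlapping pairs named above. In ATAF2ox-3 MRD1, HEI10 and CYP72C1 measured 0.410, 1.65 and 1.48 TPM, close to the 0.565, 1.91 and 1.14 of Col-0. OPR1 in ATAF2ox-3 (15.5 to 28.0 TPM) lay below Col-0 (39.8 to 54.0).

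The count between the lines was 56 and 59 without the libraries labelled ataf2-2 replicate 1 and 3, 66 without ATAF2ox-3 replicate 1 and 411 (163 higher, 248 lower) without ATAF2ox-3 replicate 3. The log2 changes of lost calls lay between 0.852 and 1.13 times those from all 9 libraries. Of the 25 named calls other than ATAF2, 4, 5 and 2 were lost without Col-0 replicates 1, 2 and 3 (adjusted p up to 0.0546, 0.0607 and 0.0748, limma). Without the libraries labelled ataf2-2 replicate 1, 2 and 3 it was 11, 6 and 9 (up to 0.142, 0.110 and 0.172), and without ATAF2ox-3 replicates 1, 2 and 3 it was 9, 5 and 1 (up to 0.167, 0.108 and 0.0504). ACS5 was lost without ATAF2ox-3 replicate 1 (adjusted p = 0.0641, limma) and without the libraries labelled ataf2-2 replicate 1 (0.0684) or 3 (0.0533), and IAA5 without the library labelled ataf2-2 replicate 1 (0.0592). Other settings also ended the calls of AT4G12490 (adjusted p up to 0.339, limma), AT4G12495 (0.206), AT3G16670 (0.122), ACS4 (0.116), ChlAKR (0.0951), NIT4 (0.0894), EXPA8 (0.0822), AT5G50335 (0.0810), OPR1 (0.0794), ACS5 (0.0604) and LTI30 (0.0550). Their log2 changes were then 0.928 to 1.55 times those given, with standard errors 1.09 times as large in the median. With voom the log2 change was 9.74 for AT4G12490 (6.29 otherwise), 6.16 for ChlAKR, 5.67 for AT3G19615 and -5.96 for AT1G17065, the last at -4.83 with a pseudocount of 0.1.

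In camera 6 of 24 lists passed in this contrast and 0 with an estimated correlation, against a median of 6.5 in simulated libraries with no list changed. Iron deficiency genes were higher in ATAF2ox-3 than in libraries labelled ataf2-2 (8 of 9 positive, mean log2 change 2.37, adjusted p = 4.27e-06; adjusted p = 0.222 with an estimated correlation). Of these genes 8 were higher adjusted over the list alone and 0 passed over all genes in limma, with BHLH38 at 4.64 and IRT1 at 1.28. Auxin response genes (14 of 16 positive, mean 0.70, adjusted p = 0.000879; 1 higher over all genes and 2 adjusted over the list alone) and ethylene signalling genes (17 of 17 positive, mean 0.32, adjusted p = 0.00278; 0 adjusted over the list alone) were higher. Both had an adjusted p = 0.622 with an estimated correlation. Nitrilases were higher (3 of 4 positive, mean 1.38, median 0.97, mean without NIT2 0.41, adjusted p = 0.0107; 2 higher over all genes, 2 higher and 1 lower adjusted over the list alone; adjusted p = 0.326 with an estimated correlation). Root tissue markers (7 of 8 negative, mean -0.54, adjusted p = 0.000856; 3 lower adjusted over the list alone) and brassinosteroid inactivation genes (5 of 7 negative, mean -0.62, median -0.32, adjusted p = 0.00385; 2 lower adjusted over the list alone) were lower. Both had an adjusted p = 0.326 with an estimated correlation. In the inactivation list CYP72C1 measured -2.96, and the other 6 genes averaged -0.23. The library means of both lines overlapped for auxin response and ethylene signalling. At the preset correlation, the mean of auxin response genes was 1.11 without the library labelled ataf2-2 replicate 2 (adjusted p = 1.56e-10, camera). It was 0.46 without ATAF2ox-3 replicate 2 (0.0403) and 0.40 without the library labelled ataf2-2 replicate 3, where the list did not pass (0.0892). The estimated correlation of these genes was 0.742. Nitrilases did not pass without ATAF2ox-3 replicate 3 (mean 1.22, adjusted p = 0.0730), with library weights (mean 1.24) or with a mean of at least 5 TPM (mean log2 change 1.298). The lists of ethylene biosynthesis (adjusted p = 0.238) and salicylic acid (0.389) did not pass, and the 18 lists without a call had adjusted p between 0.0583 and 0.975.

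ATAF2 was the 1 gene that passed in both comparisons with Col-0, and its RNA was higher in both, though ataf2-2 is described as a loss-of-function mutant. Independent lists of these sizes would share 0.0184 genes higher in both and 0.000315 lower in both, and 100 simulations of unchanged groups against the same controls shared 0 on average. As 0 of these simulations made calls in both comparisons, that last value was fixed and gives no level for the overlap of changed genes. Over 19045 genes the log2 changes of the lines had a covariance of 0.0185 and a correlation of 0.176 across genes, which are not independent replicates. Unchanged groups against shared controls gave a covariance of 0.0329 ± 0.0375 (SD over simulations) and a correlation of 0.471 ± 0.349, so the observed values were no larger than shared controls gave. The 3 Col-0 libraries are too few to be split between the comparisons, so part of any overlap may come from the shared controls.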

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

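The alternative without genes that overlap another on the opposite strand was chosen only after the results were seen. ATAF2 kept its direction and its call under the 21 alternatives run on it, between 1.23 and 1.44 on the log2 scale in libraries labelled ataf2-2 (highest adjusted p 0.0180, limma) and between 3.45 and 3.65 in ATAF2ox-3. On leaving out 1 library, counts of genes ranged from 9 to 32 for ataf2-2 against Col-0, from 8 to 122 for ATAF2ox-3 against Col-0 and from 56 to 411 between the lines. Library weights gave 69, 1943 and 2848 genes in the 3 comparisons and 21 in both lines, with a weight of 8.30 for ATAF2ox-3 replicate 1 and 0.372 for ATAF2ox-3 replicate 3. An adjusted p under 0.01 left 9, 14 and 46 genes, by its own construction, and leaving out overlapping genes left 8 for ataf2-2 against Col-0: 5 of the 16 calls were of genes left out, and 3 ended as the same p-values were adjusted over the remaining genes. Genes changed in both lines numbered 2 without a filter on low values, 2 with quantile normalization and 2 with the replicate block. Of 18 list calls 0 remained with an estimated correlation, and 15 to 30 lists passed on leaving out 1 library. Where no construction is named, the cause was not tested. The median standard error was 0.31 for the 1444 genes with a mean of 1 to 2 TPM and 0.15 for the 1567 with 100 or more; the part of depth in this was not tested.

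Replicate numbers did not pair the libraries across all 3 genotypes by their correlation over all genes. Of 9 correlations between same-numbered libraries 3 were above 0.1, from -0.342 to 0.472. Of 18 best matches in another group 7 had the same number. Between the lines, though, the correlation was 0.472 for replicate 2 and 0.433 for replicate 3, against 0.0328 for replicate 1. A structure shared by replicates of the lines is therefore not excluded, and the main fit does not allow for it. In replicate 3 of each genotype 3 lists moved alike, where chance gives 1.78. With the replicate block 17, 32 and 202 genes passed, 12, 22 and 122 of them shared with the fit without it. Of 46 named calls 28 were lost under at least 1 alternative and 0 reversed. The uncalled change of NIT1 in ATAF2ox-3 reversed with median ratio scaling (-0.0023) and library weights (-0.10), and ranged from -0.067 to 0.19 on leaving out 1 library, below 0 also without Col-0 replicate 2 (-0.023). That of DOGT1 ranged from -0.90 to 0.15, above 0 without ATAF2ox-3 replicate 2. The cause was not tested.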

Other observations

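The tests of product families and of explanations here were chosen only after the results were seen, and the splits of the samples were planned. Families of genes named by their annotated product, each with at least 10 tested members, were tested with camera at the preset correlation, which also called a median of 6 of 24 lists in simulated data with no change. In libraries labelled ataf2-2 against Col-0, 8 of 178 families were higher and 1 lower, and 0 passed with an estimated correlation. All 10 proline-rich extensin-like genes were positive (mean log2 change 0.89, adjusted p = 2.49e-09; adjusted p = 0.999 with an estimated correlation), as were 35 of 53 lipid-transfer genes (mean 0.45, adjusted p = 1.38e-07; adjusted p = 0.415 with an estimated correlation) and 36 of 51 peroxidase genes (mean 0.32, adjusted p = 8.11e-06; adjusted p = 0.999 with an estimated correlation). Of 56 SAUR-like genes 35 were negative (mean -0.28, adjusted p = 0.00197; adjusted p = 0.999 with an estimated correlation). Root tissue markers were higher in the same libraries (8 of 8 positive, mean 0.70; adjusted p = 0.284 with an estimated correlation), at 0.32, 0.26 and 0.67 relative to the mean of all 9 against -0.42, -0.09 and -0.35 in Col-0, and whether these families follow them was not tested.

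ATAF2 RNA was higher in the libraries labelled ataf2-2, for which carry-over of RNA or reads from ATAF2ox-3 would need 14.2% of the ATAF2ox-3 rise, but the other 26 genes that rose there showed a median of -1.38% of their rise (bootstrap interval -4.90% to 2.82%), which argues against it. The ratio of exon 1 to exon 2 was 0.527 in these libraries against 0.225 to 0.326 in the other 6, so a different ATAF2 transcript in this line is a candidate explanation. ATAF2ox-3 differed from Col-0 in another ratio, exon 3 to exon 2, at 0.396 to 0.429 against 0.563 to 0.668. It is therefore an uneven reference for the Col-0 exon profile below. Over the 15 other genes called between Col-0 and ataf2-2, ATAF2ox-3 showed a median share of 0.0787 of the change from Col-0 (bootstrap interval -0.0297 to 0.309) and so lay with the libraries labelled Col-0, which argues against exchanged labels of Col-0 and ataf2-2 with ATAF2ox-3 at the wild-type level of these genes. An exchange in which both lines changed these genes alike cannot be told apart from correct labels: the lowest exon of Col-0 had 0.786 of the median exon's coverage relative to ATAF2ox-3, where a lesion outside the exons would leave no trace, and the 26 genes that rose in ATAF2ox-3 had a median log2 change of -0.07 in the libraries labelled ataf2-2 against Col-0 (bootstrap interval -0.27 to 0.11, which includes 0). AT5G08760, near ATAF2 on chromosome 5, was also higher in the libraries labelled ataf2-2 (1.66 on the log2 scale). Whether both rises share a source was not tested. The genotype itself stays open, untested.

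CYP72C1, AT1G17065, HEI10 and MRD1 were higher in the libraries labelled ataf2-2, in overlapping pairs. For HEI10, the fold outside the MRD1 span was 0.0969 of the fold inside it, so reads shared with MRD1 may account for part of its rise. For CYP72C1, the exons outside the shared part rose 3.42 times, which argues against shared reads as the whole source. Its coverage was at least 4.12 times that of AT1G17065 in the shared part. That ratio decides nothing, since reads of overlapping genes on opposite strands were not fully separated. The ratio of the 3' to 5' exons of CYP72C1 was at least 1.95 in these libraries against 0.00523 to 0.243 elsewhere, so a transcript that starts inside CYP72C1 is a candidate explanation. The genotype stays open here too, untested.

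ATAF2ox-3 replicate 3 stood apart from replicates 1 and 2: glucosinolate biosynthesis genes were higher in it by 1.32 on the log2 scale (SE over genes 0.18) and flavonoid genes by 1.66 (SE 0.35). The library labelled ataf2-2 replicate 3 also exceeded its replicates 1 and 2 in these lists, by 0.48 (SE 0.087) and 0.47 (SE 0.088). Col-0 replicate 3 differed the other way, by -0.46 (SE 0.18) and -0.85 (SE 0.27). These SEs, and those below, are over genes of a list that can move together, and do not measure the spread between libraries. The depth of ATAF2ox-3 replicate 3, 4.90 gigabases, lay between those of replicates 1 and 2 (4.79 and 4.998), which argues against depth. Root markers differed by 0.44 (SE 0.18) and photosynthesis genes by 0.19 (SE 0.17), so another share of root tissue cannot be told apart from an equal one, since the second value is near its error. Morning clock genes differed by -0.68 (SE 0.26) and evening genes by -0.10 (SE 0.12), so another time of harvest cannot be told apart from the same one, for the same reason, and the morning shift was not particular to this library, at -0.59 (SE 0.29) in Col-0 replicate 3 and -0.36 (SE 0.20) in the library labelled ataf2-2 replicate 3. No other biological explanation was tested, as the labels give no difference between these replicates.

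Other libraries stood apart from their groups as well. On the second principal component, with 20.3% of the variance, Col-0 replicate 3 lay at -26.7 against 4.61 and 5.18 for replicates 1 and 2, and the library labelled ataf2-2 replicate 2 at -33.0 against -1.91 and 2.71 for replicates 1 and 3. In Col-0 replicate 3, evening clock genes were higher than in replicates 1 and 2 by 1.68 (SE over genes 0.27) and seed storage genes by 1.96 (SE 0.34). Morning clock genes differed there by -0.59 (SE 0.29), opposite to the evening genes. Another time of harvest is therefore a candidate explanation for Col-0 replicate 3, a control in both comparisons with Col-0, and was not tested further. Replicate 3 was the lowest of its group in all 3 genotypes for morning clock genes and the highest for seed storage and jasmonate genes, 3 of 24 lists where chance gives 1.78. Replicate numbers 1 and 2 had 1 such list each, also against 1.78, so these lists alone do not set replicate 3 apart. The 10 most abundant genes took 10.3%, 10.4% and 10.08% of TPM in replicate 3 of Col-0, of the libraries labelled ataf2-2 and of ATAF2ox-3, and 10.9% to 12.7% in the other 6 libraries.

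The 6 libraries of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. In ataf2-2 against Col-0 the real split gave 16 genes and the highest other 1, and 1 of the 10 splits, the real one, gave as many. In ATAF2ox-3 against Col-0 these were 29 and 11, and again 1 of 10 gave as many. In ATAF2ox-3 against ataf2-2 the real split gave 135 and the highest other 177, so 2 of 10 gave as many. That other split set the libraries labelled ataf2-2 replicate 1 and 3 with ATAF2ox-3 replicate 3 against the rest, which points to a structure of the samples beyond the genotypes.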
